A study of Danio rerio with 16 samples.

How the data were processed

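Polyadenylated RNA from whole zebrafish embryos (Danio rerio) was sequenced with a strand-directional library kit, per the labels' protocols. Embryos had been injected at 0 hours post fertilization (hpf) with a locked nucleic acid (LNA), a short antisense oligonucleotide whose modified sugars make it bind RNA tightly. The LNA either was named for BHIKHARI, an endogenous retrovirus of the zebrafish genome (Bik-1 LNA, the knockdown), or had a scrambled sequence (the control). Embryos were collected at 8, 11, 14 and 18 hpf, which gives 8 groups of 2 replicates and 16 libraries. The labels name the replicates but do not say whether they came from separate injections or clutches, so that p-values measure only the spread between these samples, which may be technical.

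The authors deposited raw read counts for each library, whole numbers per Ensembl gene and per family of transposable elements. STAR and the GRCz11 genome build are named in the submitters' processing notes. Their versions, the counting program, its strand setting and the way it assigned reads that match several places are not given in the sources used here. The counts of a repeat family sum over its copies, and reads shared by near-identical copies, by related families or by paralogous genes could be split in ways that cannot be seen in a table of counts. Counts were deposited for 32520 genes and 1036 families. The totals of the libraries ran from 4399855 to 7694887 counts, and 5.57% to 12.42% of a library's counts were in families. Genes of the mitochondrial genome had 0 counts in every library. Replicates differed by more than sampling noise in all 8 groups, with a chi-square per degree of freedom of 3.96 to 32.6, so none was treated as a repeat deposit of the same library.

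Gene symbols came from a table of Ensembl identifiers, which gave a symbol to 29201 genes, many of them in the capitals of the human ortholog. It gave 1719 symbols to more than 1 gene each, 6136 genes in all, and such genes are named here with their identifier. A RefSeq table built on the GRCz12tu assembly was used for synonyms only, and no coordinates are reported because no genome of the build was used here. Of 721 list members fixed before the data were examined, 528 matched a symbol, 150 the human-style symbol without its paralog letter, 8 a RefSeq synonym and 35 none. None of the symbols listed as derived from retroviral Gag matched, so that group was not tested, and neither was the group of mitochondrial genes.

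Genes and families were tested together with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F-test with robust dispersion, TMM scaling and the filter of filterByExpr on the 8 groups. The filter kept 17756 features, 16894 genes and 862 families, which held at least 99.76% of each library's counts. All 16 libraries entered a single fit with 1 mean per group and 8 residual degrees of freedom. The biological coefficient of variation was 0.177. The median standard error (SE) of a log2 fold change was 0.33 for a single time and 0.17 for the average over the 4 times. Contrasts compared knockdown with control at each time and on average, tested whether the knockdown effect differed between times, and compared successive times in the controls. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features tested. All adjusted p-values for genes and families below are from this edgeR test unless another tool is named. Counts-per-million values (CPM) were scaled by TMM, except those of ERV1-N3 families, which were scaled by the library total alone. For a gene with 0 counts in all libraries of a group, a lower bound of the fold was computed with 3 counts over the group in place of 0, and such bounds cover counting error only.

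Gene lists with at least 5 tested members, 34 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, again with a correlation estimated from the data, and with fry. Camera asks whether a list moves relative to all other genes, and fry whether its genes move on balance in a direction, without comparing them with other genes. List p-values were adjusted over the 34 lists of a comparison. The result of 1 list, and of some genes, is not reported here.

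Genes named for the knockdown comparisons followed a rule fixed before the data were examined. It took the largest rises and falls among called genes with a mean of at least 1 CPM whose libraries or times moved the same way, the called members of each list with the lowest p, every BHIKHARI family and the called families with the largest change. For the change in effect over time it took the genes with the lowest p. Names that only repeat a clone or an accession were left out.

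The tests were run on simulated counts with the real means and library sizes, in which 67 features changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. At 8 hpf edgeR recovered 4.5% of features changed 1.5-fold, 25.4% at 2-fold and 50% at 4-fold, with 0 false calls among 53. For the average over times it recovered 47.8%, 65.7% and 86.4%, with 7 false calls among 140. For a difference between times it recovered 0%, 4.5% and 42.4%, with 4 false calls among 35. For the control interval from 8 to 11 hpf it recovered 0%, 28.4% and 75.8%, with 4 false calls among 73. Simulated data with no change gave 0 calls. Of 5 simulated lists shifted 1.5-fold, camera recovered 5 with either correlation, and fry recovered 5 with 2 false calls. Among 15 other lists camera made 1 false call for the preset correlation and 0 for the estimated. The simulated genes varied independently and the lists held random genes. These runs therefore cannot show whether the preset correlation suits the real lists.

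Alternatives were other scalings (RLE and upper quartile), no filter beyond 1 count, a filter of at least 1 CPM in at least 4 libraries and DESeq2 1.42.0. Others were a block for the replicate number, across or within times, the compared groups fitted alone, genes fitted without families, and each library left out in turn. After the data had been seen, the average over 11, 14 and 18 hpf only was added, because libraries of 8 hpf stood apart. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.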

Results

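RNA from whole zebrafish embryos was counted in 16 libraries, 2 each for scrambled LNA (control) and Bik-1 LNA (knockdown) at 8, 11, 14 and 18 hpf, a span from gastrulation to somite stages. Totals ran from 4399855 counts (knockdown 14 hpf replicate 1) to 7694887 counts (knockdown 11 hpf replicate 2). Developmental time was the main axis of variation: the first principal component held 65.9% of the variance and the second 12.8%. On the first component the controls went from -118.5 and -137.7 at 8 hpf to 120.2 and 122 at 18 hpf, and the knockdown mean lay on the side of earlier times at all 4 times. The groups overlapped at 8 hpf (knockdown -125.5 and -141) and at 11 hpf (knockdown -8 and -44.5, controls -4 and -26.6). At 14 hpf the knockdown libraries lay at 18.3 and 32.4 and the controls at 40.5 and 48.6. At every time each knockdown library lay on the earlier side of the control with its replicate number. Whether these numbers pair the samples is not known. At 8 hpf, 2 libraries stood apart. In control replicate 1 the families held 12.42% of counts against 8.94% in replicate 2, with the retroviral family ERV1-N3-I_DR at 40500 against 18400 CPM. The knockdown replicates differed the same way but less, at 9.94% against 8.75% and 29300 against 20600 CPM. In knockdown replicate 1, 3 genes without a symbol held 4.83% of counts, against 0.12% in replicate 2 and at most 0.2% in any other library.

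The first question was whether the Bik-1 LNA lowered BHIKHARI RNA. The long terminal repeats of the retrovirus, counted as the family BHIKHARI_LTR, fell at all 4 times. In controls they stood at 2810 and 2820 CPM in the replicates at 8 hpf, 437 and 323 at 11 hpf, 214 and 216 at 14 hpf, and 98.9 and 104 at 18 hpf. The knockdown libraries had 677 and 751 CPM at 8 hpf, 124 and 95.5 at 11 hpf, 51.5 and 53.5 at 14 hpf, and 36.2 and 34.8 at 18 hpf. The log2 fold change was -1.98 (SE 0.14, adjusted p = 1.5e-06) at 8 hpf, -1.80 (SE 0.14, adjusted p = 7.9e-06) at 11 hpf, -2.03 (SE 0.14, adjusted p = 2.1e-06) at 14 hpf and -1.52 (SE 0.15, adjusted p = 2e-04) at 18 hpf. Averaged over the times it was -1.83 (SE 0.07, adjusted p = 1.3e-10), which left 28.1% of the control level. The 11 hpf call was lost when the groups of that time were fitted alone, with the log2 fold change still -1.80 and an adjusted p of 1.

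**Figure D1:**
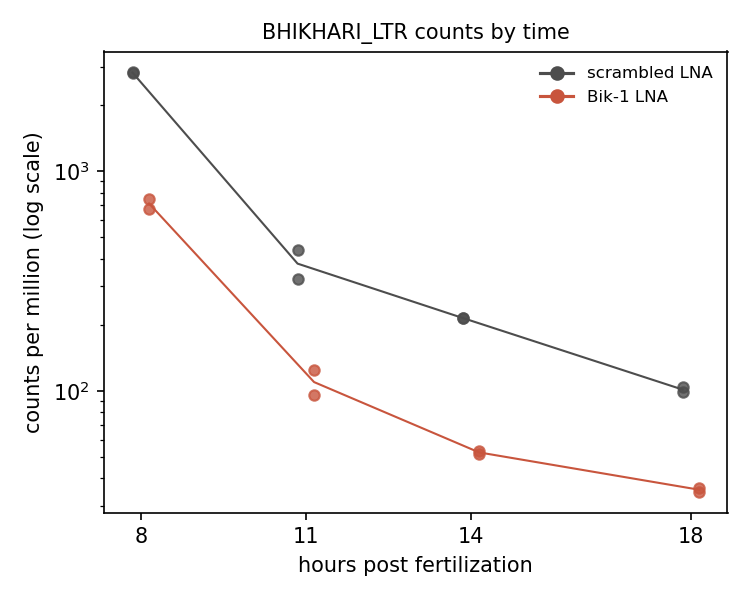
CPM of BHIKHARI_LTR (log scale) against hours post fertilization for scrambled LNA and Bik-1 LNA. Each point is a library (2 per group) and lines join group means; the knockdown libraries lie below the controls at all 4 times, at 677 and 751 against 2810 and 2820 CPM at 8 hpf.

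The internal part of the retrovirus, which holds its coding sequence, was counted as BHIKHARI_I-int. It fell on average over the 4 times, with a log2 fold change of -1.37 (SE 0.19, adjusted p = 0.0082). At single times it was lower in the knockdown without passing the threshold: 545 ± 18.2 against 2030 ± 53 CPM at 8 hpf (mean ± SD, n = 2, adjusted p = 0.078), 33.8 ± 0.245 against 92.7 ± 4.61 CPM at 14 hpf (adjusted p = 0.66), and log2 fold changes of -1.05 at 11 hpf and -1.09 at 18 hpf (adjusted p = 1 and 0.99). The BHIKHARI_I-int average call was lost over 11, 14 and 18 hpf only (log2 fold change -1.2, adjusted p = 0.078). Without knockdown 11 hpf replicate 1 or 2, BHIKHARI_I-int passed at 8 hpf (adjusted p = 0.00032) and at 14 hpf (adjusted p = 0.025), and by DESeq2 it passed at 8 hpf (adjusted p = 0.00022). The 8 families named BHIKHARI-2 to BHIKHARI-5 did not pass the threshold in any knockdown comparison, with average log2 fold changes from -0.52 (BHIKHARI-5-LTR_DR, SE 0.21, adjusted p = 0.27) to 0.56 (BHIKHARI-3-I_DR, SE 0.23, adjusted p = 0.28).

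Few other repeat families were called. Among families with an unadjusted p under 0.05, BHIKHARI included, 60 were lower and 22 higher on average over the times. The counts lower and higher were 28 and 27 at 8 hpf, 17 and 11 at 11 hpf, 27 and 6 at 14 hpf, and 26 and 7 at 18 hpf. At 11, 14 and 18 hpf their totals were smaller than chance alone would give among 862 families. The median log2 fold change of all families was -0.107 at 14 hpf and -0.065 at 18 hpf, against 0.006 and 0.004 for genes. At 8 hpf, 2 of the 862 families were called, BHIKHARI_LTR and the DNA transposon DNA-8-3_DR, at -0.74 (SE 0.15, adjusted p = 0.035). At 11, 14 and 18 hpf BHIKHARI_LTR was the 1 family called. On average over the times 8 families were called, 1 higher and 7 lower. Beside both BHIKHARI parts these included Gypsy85-LTR_DR at -0.94 (SE 0.17, adjusted p = 0.0085), Gypsy37-LTR_DR at -0.82 (SE 0.18, adjusted p = 0.028), Gypsy117-LTR_DR at -0.57 (SE 0.11, adjusted p = 0.0091) and ERV3_DR_LTR at -0.46 (SE 0.11, adjusted p = 0.042), all retrotransposon repeats, and the Pao element CATCH2I_DR rose by 0.49 (SE 0.1, adjusted p = 0.021). Over 11, 14 and 18 hpf only, 1 family was called. The average count was 29 without knockdown 11 hpf replicate 1, 5 without control 14 hpf replicate 2 and 4 without control 18 hpf replicate 2. At 8 hpf 1 family was called without control 8 hpf replicate 2, knockdown 8 hpf replicate 1, control 14 hpf replicate 1 or 2, or knockdown 18 hpf replicate 1 or 2. At 11 hpf 2 families were called without knockdown 11 hpf replicate 1, and at 14 hpf 2 without either knockdown library of 11 hpf.

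At 8 hpf, late in gastrulation, 3 listed genes of the future forebrain and eye were called lower in the knockdown. The homeobox gene rx3, needed for eye formation, stood at 5.79 ± 1.53 CPM against 28.1 ± 5.86 in controls (mean ± SD, n = 2), a log2 fold change of -2.28 (SE 0.4, adjusted p = 0.024). FEZF2, a zinc finger factor of the forebrain, fell to 15.4 ± 0.927 from 51 ± 8.44 CPM (-1.72, SE 0.21, adjusted p = 0.00074). PAX6 (1 of the 2 genes listed under that symbol, ENSDARG00000045936), a regulator of eye and brain, fell to 18.7 ± 0.397 from 46.1 ± 12.8 CPM (-1.30, SE 0.22, adjusted p = 0.014). In the list of anterior neural plate and eye genes 3 of 23 members fell, 7 adjusted over the list alone, and none rose. The list's median log2 fold change was -0.66, or -0.69 with members at 0 counts set to their bound. It moved down by camera with the preset correlation (adjusted p = 4.2e-05) but not with an estimated correlation (adjusted p = 0.47) or by fry (adjusted p = 0.16), nor without control 8 hpf replicate 1 (adjusted p = 0.051).

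In all, 59 of the 16894 genes were called at 8 hpf, 54 lower and 5 higher. An unadjusted p under 0.05 was seen for 1576 genes, 933 lower and 643 higher. Falls were 91.5% of the 59 called genes. They were 68.8% of 314 with no filter beyond 1 count and 69.3% of 603 with a replicate block within each time. PPP1R1B, a phosphatase regulator of dopamine signalling, had 0 counts in the knockdown and 65 in the controls, at least 21.1-fold lower (adjusted p = 0.0069). The filamin-like gene flnbl had 0 against 21 counts, at least 6.82-fold lower (adjusted p = 0.027). Other falls were rsrc1 (-2.23, SE 0.41, adjusted p = 0.033), the ubiquitin ligase PDZRN3 (1 of 2 genes, ENSDARG00000073869; -2.08, SE 0.3, adjusted p = 0.0042), RALGPS2 (-2.07, SE 0.41, adjusted p = 0.041), the cadherin cdh26.1 (-1.91, SE 0.38, adjusted p = 0.034) and GFUS, which makes GDP-fucose (1 of 2 genes, ENSDARG00000039666; -1.79, SE 0.29, adjusted p = 0.012). VANGL2, a planar cell polarity protein of convergence and extension, fell by 0.56 (SE 0.12, adjusted p = 0.046), the single member of 38 to pass in the list of cell migration and adhesion in gastrulation. That list was lower by fry (adjusted p = 0.019) and did not pass by camera (adjusted p = 0.27). The cofactor of histone methylation atf7ip fell by 0.65 (SE 0.13, adjusted p = 0.038), the single member of 23 in the list of transposon silencing.

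The 5 rises at 8 hpf were the muscle tropomodulin TMOD4 (1.84, SE 0.31, adjusted p = 0.012), the cryptochrome cry3a (1.35, SE 0.15, adjusted p = 0.00042), the histone gene hist2h2l (1.2, SE 0.23, adjusted p = 0.031) and the poly(A)-binding proteins pabpc1b (0.92, SE 0.16, adjusted p = 0.015) and pabpc1a (0.44, SE 0.09, adjusted p = 0.046). Of the 17 tested members of the list of Nodal signalling and mesendoderm, the tissue in which BHIKHARI is known to be active, 0 were called by edgeR, over all genes or adjusted over the list alone, and their median log2 fold change was -0.08 (camera adjusted p = 0.56). The 54 genes that fell at 8 hpf had a median log2 fold change of -1.23 there. All 54 were below 0 at 11 hpf, 47 at 14 hpf and 42 at 18 hpf, with medians of -0.52, -0.38 and -0.17, while 48.7% to 49.4% of all genes were below 0 at these times. The count of 59 was 16 without knockdown 8 hpf replicate 1, 27 without control 8 hpf replicate 1, 36 without knockdown 8 hpf replicate 2 or either control library of 14 hpf, and 120 and 121 without knockdown 11 hpf replicate 1 and 2. DESeq2 called 110 genes, no filter beyond 1 count gave 314, and the 8 hpf groups fitted alone gave 3.

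**Figure D2:**
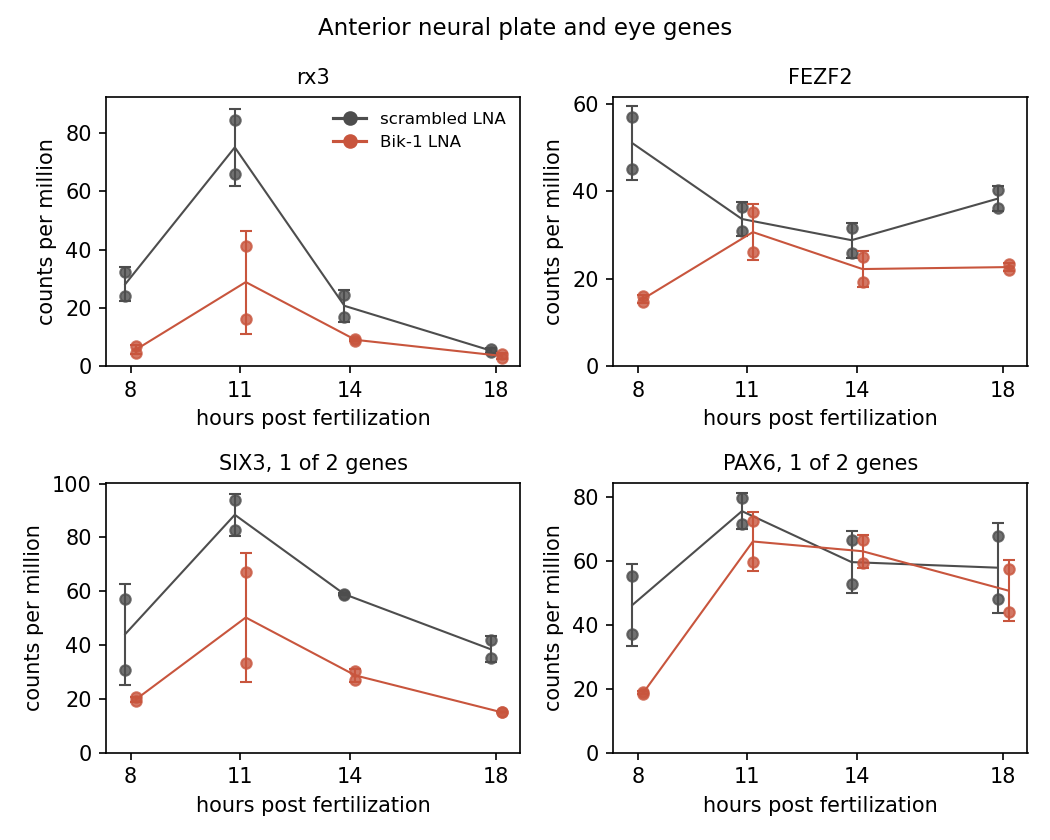
CPM of rx3, FEZF2, SIX3 (ENSDARG00000054879) and PAX6 (ENSDARG00000045936) against hours post fertilization for scrambled LNA and Bik-1 LNA. Points are libraries (2 per group), lines join means and bars are SD; at 8 hpf the knockdown means of rx3 and FEZF2 were 5.79 and 15.4 CPM against 28.1 and 51 CPM in controls.

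At 11 hpf, when the first somites form, edgeR called 117 genes with a replicate block within each time. Without a block no gene passed the threshold in edgeR, and DESeq2 called 9. An unadjusted p under 0.05 was seen for 795 genes, fewer than chance alone would give among the 16894 tested. Lists nevertheless moved together by camera with the preset correlation. Anterior neural plate and eye genes (adjusted p = 0.016, 16 of 23 below 0, 1 fall adjusted over the list alone), blood and vessel genes (adjusted p = 0.016, 19 of 23 below 0) and ribosomal protein genes (adjusted p = 0.0063, 74 of 79 below 0, median -0.09) lay lower. With an estimated correlation none of these lists passed (adjusted p = 0.58, 0.58 and 0.89). Without knockdown 11 hpf replicate 2, whose ribosomal protein share was 6.28% against 7.73% in replicate 1, the ribosomal genes moved up (adjusted p = 0.027) and the eye (0.93) and blood (0.71) lists were lost. Without control replicate 1 the eye (0.12), blood (0.26) and ribosomal (0.35) lists were lost, and without control replicate 2 the eye list (0.12). Without knockdown 11 hpf replicate 1, 75 genes were called, 1 without control 11 hpf replicate 1, and 92 with no filter beyond 1 count.

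At 14 hpf ribosomal protein genes lay lower in the knockdown, with 78 of 79 members below 0 and a median log2 fold change of -0.23 (camera adjusted p = 3.5e-12 with the preset and adjusted p = 0.67 with an estimated correlation). Their share of counts was 7.93% and 8.96% in the knockdown libraries and 9.03% and 10.22% in the controls. Anterior neural plate and eye genes lay lower, with 6 falls and 1 rise adjusted over the list alone (adjusted p = 0.013 and, estimated, adjusted p = 0.67), as did neurogenesis genes, with 21 of 28 below 0 (adjusted p = 0.014 and, estimated, adjusted p = 0.67). With a replicate block within each time edgeR called 305 genes. Without a block no gene passed in edgeR, and DESeq2 called 10. An unadjusted p under 0.05 was seen for 958 genes, little more than chance alone would give among the 16894 tested. The count was 13 without either knockdown library of 11 hpf, 55 with the 14 hpf groups fitted alone and 144 with no filter beyond 1 count. The eye list was lost without control 14 hpf replicate 1 (adjusted p = 0.12) or knockdown 14 hpf replicate 1 (0.064), and the neurogenesis list without control 14 hpf replicate 2 (0.097) or knockdown 14 hpf replicate 1 (0.18).

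At 18 hpf the keratin gene krt18a.1, of simple and embryonic surface epithelia, was the 1 gene called. It rose by 0.84 on the log2 scale (SE 0.1, adjusted p = 0.0036), from 669 ± 29.7 to 1200 ± 2.71 CPM (mean ± SD, n = 2). Ribosomal protein genes lay lower (77 of 79 below 0, median -0.19, camera adjusted p = 2.1e-10 with the preset and adjusted p = 0.94 with an estimated correlation), at 12.27% and 12.8% of counts in the knockdown against 13.55% and 14.45% in controls. Anterior neural plate and eye genes lay lower too (19 of 23 below 0, 5 falls adjusted over the list alone, adjusted p = 2.6e-05, estimated adjusted p = 0.94). Genes of the yolk syncytial layer, which feeds the embryo from the yolk, lay higher (20 of 25 above 0, adjusted p = 0.039, estimated adjusted p = 0.94). That call was lost without control 8 hpf replicate 1 (0.057) or 2 (0.058), control 18 hpf replicate 1 (0.089) or 2 (0.23), or knockdown 18 hpf replicate 1 (0.4). With a replicate block within each time edgeR called 115 genes. Without a block, 766 of the 16894 genes had an unadjusted p under 0.05, fewer than chance alone would give, and DESeq2 called 5. The edgeR count was 0 without any 1 of the 4 libraries of 18 hpf, 5 without either knockdown library of 11 hpf, 115 with the 18 hpf groups fitted alone and 121 with no filter beyond 1 count.

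Averaged over the 4 times, 4 anterior neural plate and eye genes were called lower in the knockdown. SIX3 (1 of 2 genes, ENSDARG00000054879), a homeobox gene of forebrain and eye, fell by 1.09 on the log2 scale (SE 0.15, adjusted p = 0.0028), rx3 by 1.36 (SE 0.2, adjusted p = 0.0035), FEZF2 by 0.75 (SE 0.1, adjusted p = 0.0014) and ZIC1, a zinc finger gene of the neural plate, by 0.66 (SE 0.14, adjusted p = 0.029). These 4 of the 23 tested members fell, 9 adjusted over the list alone. The list moved down by camera with the preset correlation (adjusted p = 1.8e-07, median -0.45) and by fry (adjusted p = 0.034, lost at 0.12 over 11, 14 and 18 hpf only), but not with an estimated correlation (adjusted p = 0.61). Cyclin G1 CCNG1 (0.53, SE 0.09, adjusted p = 0.0074), the apoptosis inducer pmaip1 (0.63, SE 0.13, adjusted p = 0.023) and the caspase casp8 (0.90, SE 0.2, adjusted p = 0.032) rose. CCNG1 had a higher mean in the knockdown at each of the 4 times.

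In all, 281 genes were called on average, 223 lower (79.4%) and 58 higher. Of these, 270 had the same direction at all 4 times, which choosing genes by their average over those times favours. An unadjusted p under 0.05 was found for 2659 genes, 1385 lower and 1274 higher, so the excess of falls was among the called genes. It was small among genes called with a replicate block within each time (53.1% of 2034). The nuclear noncoding RNA malat1 fell by 1.99 (SE 0.29, adjusted p = 0.013), from 578 ± 89.1 to 91.8 ± 45.8 CPM at 8 hpf and from 993 ± 271 to 334 ± 195 CPM at 18 hpf (mean ± SD, n = 2). PPP1R1B (adjusted p = 0.005) stood at 1.21 ± 0.493 against 5.73 ± 1.65 CPM in controls at 14 hpf. The homeobox gene hmx1, expressed in the developing eye and ear, stood at 2.15 ± 0.367 against 11.7 ± 4.39 CPM at 18 hpf (adjusted p = 0.04), and the calcium channel gene cacna1aa at 1.73 ± 0.179 against 5.11 ± 0.0732 CPM (adjusted p = 0.0028). The collagen gene COL1A1 stood at 1.47 ± 0.361 against 5.29 ± 0.0529 CPM at 14 hpf (adjusted p = 0.021). The receptor genes gfra1a (-2.18, SE 0.49, adjusted p = 0.034) and ADGRL3 (1 of 2 genes, ENSDARG00000090624; -2.17, SE 0.49, adjusted p = 0.032) fell at levels of 5.3 CPM or less. FBXL7 fell as well (adjusted p = 0.035), with 0 against 10 counts at 14 hpf, at least 2.74-fold lower.

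The largest average rises included isg15, an interferon-induced ubiquitin-like protein (adjusted p = 0.028). It stood at 10.7 ± 0.934 against 5.4 ± 1.63 CPM at 8 hpf, and at 18 hpf had 15 counts against 0, at least 4.77-fold higher. It was the 1 member to rise among 13 interferon and antiviral genes, 2 adjusted over the list alone, a list that moved up with the preset correlation (adjusted p = 0.028) and not with an estimated correlation (adjusted p = 0.61). ANKRD34B (1 of 2 genes, ENSDARG00000061641; adjusted p = 0.014) had 9 counts against 0 at 18 hpf, at least 2.86-fold higher. Other rises were the lysosomal sulfatase gnsb (1.36, SE 0.27, adjusted p = 0.018), the glutamate cyclase DGLUCY (1.24, SE 0.2, adjusted p = 0.0047), caprin2 (1.16, SE 0.26, adjusted p = 0.028), the ephrin EFNA3 (1.16, SE 0.22, adjusted p = 0.012), fam83fa (1.02, SE 0.24, adjusted p = 0.042) and SH2D3C (1 of 2 genes, ENSDARG00000028099; 0.99, SE 0.22, adjusted p = 0.028).

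Other lists had few called members on average. Ribosomal protein genes lay lower (75 of 79 below 0, median -0.14, camera adjusted p = 7.4e-11 with the preset and adjusted p = 0.75 with an estimated correlation), with 1 fall, RPL31 (-0.27, SE 0.06, adjusted p = 0.04), and 3 adjusted over the list alone. Neurogenesis genes lay lower with no member called (22 of 28 below 0, adjusted p = 0.049, estimated adjusted p = 0.75). That call was lost without control 8 hpf replicate 1 (0.24), 11 hpf replicate 1 (0.076), 14 hpf replicate 2 (0.099) or 18 hpf replicate 1 (0.099), or knockdown 8 hpf replicate 2 (0.12), 11 hpf replicate 2 (0.14), 14 hpf replicate 1 (0.12) or 18 hpf replicate 2 (0.12). With a filter of at least 1 CPM in at least 4 libraries, the average calls of the Neurogenesis list (0.058) and of the Interferon and antiviral response list (0.068) were lost, and with RLE size factors that of Neurogenesis (0.054). Of 29 epidermal and enveloping layer genes, krt18a.1 (0.40, SE 0.05, adjusted p = 0.0013) and krt8 (0.32, SE 0.06, adjusted p = 0.013) rose and TP63, of the basal epidermis, fell (-0.37, SE 0.09, adjusted p = 0.04). Single members changed in other lists: the angiopoietin receptor tek fell (-0.74, SE 0.17, adjusted p = 0.036), as did fibronectin FN1 (1 of 2 genes, ENSDARG00000019815; -0.28, SE 0.05, adjusted p = 0.011) and atf7ip (-0.30, SE 0.06, adjusted p = 0.026). The homeobox gene IRX1 (1 of 2 genes, ENSDARG00000056594; 0.31, SE 0.05, adjusted p = 0.0074) and XBP1, of the unfolded protein response (0.29, SE 0.05, adjusted p = 0.011), rose. Of the 17 Nodal and mesendoderm genes, 0 were called by edgeR, over all genes or over the list alone (median 0.03, camera adjusted p = 0.66).

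The average count of 281 was 55 over 11, 14 and 18 hpf only, where 10 of 39 named calls were kept. The share of falls on average was 53.3% of 1038 called genes with no filter beyond 1 count and 62.6% of 965 without knockdown 11 hpf replicate 1. The count was 965 without knockdown 11 hpf replicate 1, 156 and 159 without control 14 hpf replicate 1 and 2, 144 and 176 without knockdown 14 hpf replicate 1 and 2, 169 and 145 without control 18 hpf replicate 1 and 2, and 175 and 158 without knockdown 18 hpf replicate 1 and 2.

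**Figure D3:**
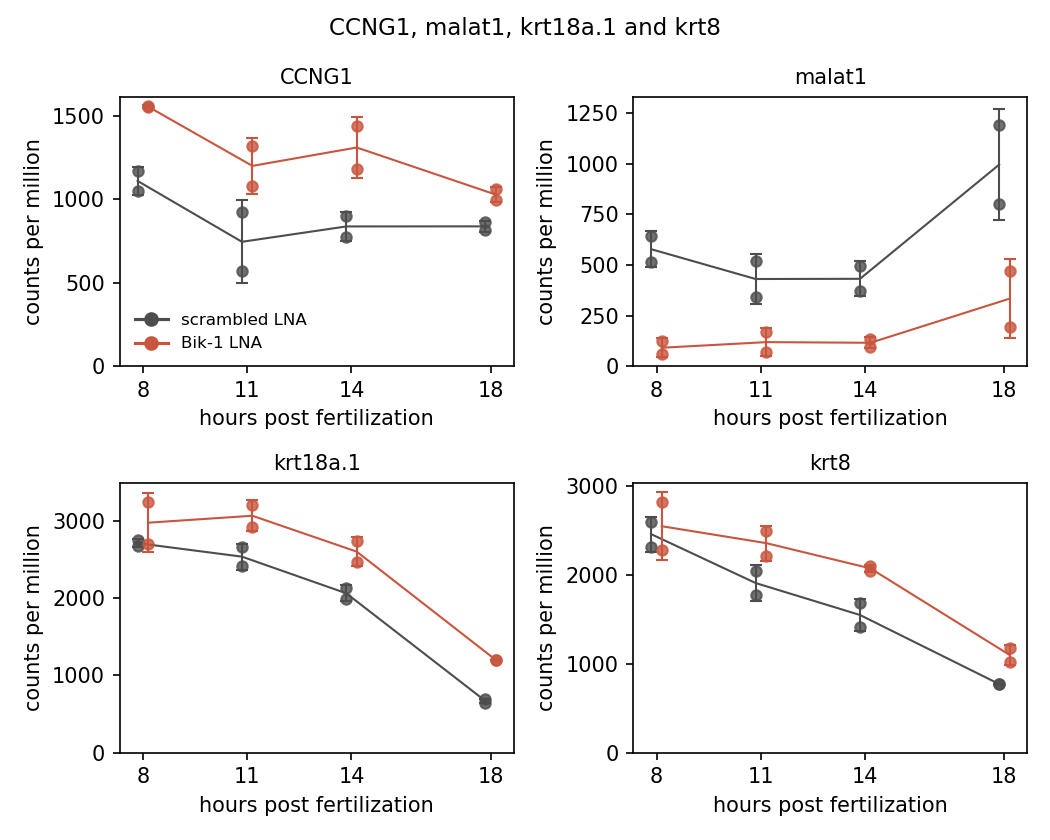
CPM of CCNG1, malat1, krt18a.1 and krt8 against hours post fertilization for scrambled LNA and Bik-1 LNA. Points are libraries (2 per group), lines join means and bars are SD; at 18 hpf the means of krt18a.1 were 1200 CPM in the knockdown and 669 in controls, and those of malat1 334 and 993 CPM.

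Whether the effect of the knockdown differed between times was tested with an interaction of treatment and time. With a replicate block within each time edgeR called 93 genes. Without a block no gene passed in edgeR, DESeq2 called 3, and no filter beyond 1 count gave 77. An unadjusted p under 0.05 was seen for 457 genes, fewer than chance alone would give among the 16894 tested. The gene ranked first by edgeR was GID8 (1 of 2 genes, ENSDARG00000037589), of a ubiquitin ligase complex, at an adjusted p of 0.29. Its log2 fold change was -1.42 at 8 hpf (adjusted p = 6.7e-05) and -0.42, -0.40 and -0.11 at 11, 14 and 18 hpf. FEZF2 (adjusted p = 0.88) went from -1.72 at 8 hpf to -0.14 at 11 hpf and -0.76 at 18 hpf. The laminin gene lamc1 went from -1.25 to -0.09 and GFUS (ENSDARG00000039666) from -1.79 to 0.50 between 8 and 18 hpf (both adjusted p = 0.88). ARHGAP5, SERINC5, haus8 and ZNF609 (1 of 2 genes, ENSDARG00000104530) came next, each lower at 8 hpf than at later times and each at an adjusted p of 0.88. Ribosomal protein genes alone among the 34 lists had a different effect by camera with the preset correlation, more negative at 14 than at 8 hpf (adjusted p = 8.2e-05, estimated adjusted p = 0.79) and at 18 than at 8 hpf (adjusted p = 0.0041, estimated adjusted p = 0.92). By fry the list of cell migration and adhesion in gastrulation had a more positive effect at 18 than at 8 hpf (adjusted p = 0.018, 27 of 38 members above 0), while by camera it did not pass (adjusted p = 0.14, estimated adjusted p = 0.66).

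By edgeR 59, 0, 0 and 1 genes had been called at 8, 11, 14 and 18 hpf, and over the 6 pairs of times 0 calls were shared. Any pair with 11 or 14 hpf could only give 0, and 8 and 18 hpf could share at most 1. This count therefore cannot show whether the effects at different times share genes. DESeq2 gave 9 shared calls. With a replicate block within each time 603, 117, 305 and 115 genes were called, and their overlap is not given here. The log2 fold changes of pairs of times, which share no library, correlated across genes with Pearson's r from 0.04 (8 and 18 hpf) to 0.237 (11 and 14 hpf) and Spearman's rho from 0.114 to 0.342; genes are not independent replicates, and no p is given. Without knockdown 11 hpf replicate 1 the shared calls came to 47, and without replicate 2 to 7.

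The controls give the background of normal development. From 8 to 11 hpf 5284 genes changed, 3248 up and 2036 down. Genes of regional brain identity rose, in 16 of 25 midbrain and hindbrain cases (camera adjusted p = 2e-06, with an estimated correlation adjusted p = 0.19). The hatching enzyme he1.2 rose by 9.23 (SE 0.38, adjusted p = 3.8e-10) and hoxa9b by 6.50 (SE 0.4, adjusted p = 2.9e-08). The slow muscle myosin smyhc1 went from 0 to 430 counts, at least 138-fold higher. Ribosomal protein genes rose in 74 of 79 cases (adjusted p = 1.8e-12, estimated adjusted p = 0.52). Nodal and mesendoderm genes fell in 12 of 17 cases (adjusted p = 7.3e-08, estimated adjusted p = 0.071), among them tdgf1 (-2.60, SE 0.2, adjusted p = 2.3e-07) and GSC (-2.63, SE 0.27, adjusted p = 4.8e-06). The maternal pluripotency gene pou5f3 fell by 4.28 (SE 0.5, adjusted p = 0.00024) and the endoderm gene sox32 by 5.42 (SE 0.55, adjusted p = 1.6e-05). BHIKHARI_LTR fell by 2.89 (SE 0.14, adjusted p = 2.2e-09) and BHIKHARI_I-int by 3.91 (SE 0.39, adjusted p = 8.7e-05). The count was 2716 without control 8 hpf replicate 2 and 3122 without control 11 hpf replicate 1.

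From 11 to 14 hpf 463 genes changed in controls, 346 up and 117 down. Somite and skeletal muscle genes rose in 10 of 31 cases (camera adjusted p = 1.1e-11, estimated adjusted p = 0.13), among them tropomyosin tpma (1.79, SE 0.24, adjusted p = 0.00085). The retinal homeobox gene rx1 rose by 4 (SE 0.55, adjusted p = 0.0012) and FEZF1 by 3.77 (SE 0.64, adjusted p = 0.0059), while OTX2 of forebrain and midbrain fell by 1.03 (SE 0.12, adjusted p = 4e-04). The Nodal inhibitor lft1 fell by 4.03 (SE 0.43, adjusted p = 0.00015) and the endoderm gene SOX17 by 4.9 (SE 1.05, adjusted p = 0.019). BHIKHARI_LTR fell by 0.82 (SE 0.14, adjusted p = 0.003). The count was 293 and 114 without control 11 hpf replicate 1 and 2, 209 and 98 without control 14 hpf replicate 1 and 2, and 757 and 774 without knockdown 11 hpf replicate 1 and 2, which share in the estimate of the spread.

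From 14 to 18 hpf 2024 genes changed in controls, 1360 up and 664 down, and muscle led the rises. The fast myosin genes myhz1.3 and myhz1.1 rose by 11.76 (SE 0.43, adjusted p = 3.1e-10) and 10.98 (SE 0.47, adjusted p = 2.3e-09), and myhz2 went from 0 to 478 counts, at least 172-fold higher. In the somite and muscle list 24 of 31 members rose and 1 fell (camera adjusted p = 4.4e-18, estimated adjusted p = 0.04). In other lists 11 of 25 presomitic and tailbud genes fell (adjusted p = 4.2e-07, estimated adjusted p = 0.04) and 10 of 22 genes of glycolysis and hypoxia rose (adjusted p = 1.5e-06, estimated adjusted p = 0.015). Embryonic globin genes rose, hbae3 by 4.37 (SE 0.43, adjusted p = 8.5e-06) and hbbe3 by 7.50 (SE 0.59, adjusted p = 2.8e-05). The keratins krt18a.1 and krt8 fell by 1.63 (SE 0.11, adjusted p = 6.2e-08) and 1.01 (SE 0.13, adjusted p = 5.8e-05), rx3 by 1.91 (SE 0.4, adjusted p = 0.0068) and the small heat shock gene HSPB1 by 2.96 (SE 0.13, adjusted p = 3.1e-10). BHIKHARI_LTR fell by 1.08 (SE 0.14, adjusted p = 7.4e-05). The count was 636 and 811 without control 14 hpf replicate 1 and 2, 1060 and 798 without control 18 hpf replicate 1 and 2, and 4093 with these groups fitted alone.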

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

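The comparisons of the eye list with the midbrain and hindbrain list and with the neurogenesis list and the question of an LNA effect other than on BHIKHARI are the tests chosen only after the results were seen. Ribosomal protein genes drew attention because the effect of the Bik-1 LNA on them differed between times by camera with the preset correlation. It was more negative at 14 than at 8 hpf (adjusted p = 8.2e-05, median difference -0.20 on the log2 scale, 76 of 79 members below 0) and more negative at 18 than at 8 hpf (adjusted p = 0.0041, median difference -0.16, 72 of 79 below 0). With an estimated correlation neither difference passed (adjusted p = 0.79 and 0.92).

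The first pattern weighed is the 281 genes called on average, of which 79.4% were lower in the knockdown. For this count, 4 of 100 regroupings within times, the real one included, gave as many genes, and the highest other count was 1315. This would exclude chance only if the libraries of a time were interchangeable. Same-numbered libraries correlated in their deviations at r of 0.37 at 8 hpf and 0.61 at 11 hpf, so chance is not excluded. The 3 regroupings with more genes were among 30 that parted the 11 hpf libraries by replicate number, so a structure of those samples enters some of these counts but not all. The lowest share of falls under the other scalings was 75.4%, which argues against the choice among these scalings as the source of the excess. All of them assume that most genes are unchanged, so an effect of scaling that they share was not tested. The excess was small with no filter beyond 1 count (53.3% of 1038 genes) and with a replicate block within each time (53.1% of 2034). Among genes with an unadjusted p under 0.05 it was small too (1385 of 2659 lower). Slower development of the knockdown embryos stays open. Of the called genes 69.4% (95% interval 63.6% to 74.7%) differed in the direction of earlier controls, between the bounds set in advance. Of all genes used 59.5% did. The interval treats genes as independent and leaves out the spread between libraries, so it cannot show that these shares differ.

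The second pattern is the lower level of anterior neural plate and eye genes, a list call that did not hold with an estimated correlation (adjusted p = 0.61), and chance cannot be excluded for the count of 5 lists called on average (40 of 100 regroupings, highest other 12). The median of this list was below that of the midbrain and hindbrain list by -0.35 on the log2 scale. The 95% bootstrap interval over members was -0.71 to -0.03. It treats genes as independent and leaves out the spread between libraries, so loss of all neural tissue alike stays open. The midbrain and hindbrain median itself was -0.1 on average (interval -0.2 to 0.12). At 8, 11, 14 and 18 hpf it was -0.12, -0.05, 0.1 and 0.16, where the eye list had -0.66, -0.19, -0.37 and -0.29. A fall shared with neurogenesis genes stays open, since their median was also lower (-0.20, interval -0.33 to -0.09) and the difference of -0.25 had an interval of -0.54 to 0.1. Slower development stays open as a cause of the lower eye list. Taking out the straight-line trend of the controls over time removed 34.7% of the median, from -0.45 to -0.29. This lay between the bounds set in advance, and the interval over members of what remained was -0.41 to -0.17. By that trend 10 members fell in controls, and 7 of them were lower in the knockdown, where a delay would make them higher. Of the 13 members that rose in controls, 11 were lower, as a delay would make them. A straight line cannot follow genes that peak within the window, so neither the remainder nor these counts decide the question. In controls rx3 stood at 32.3 and 24 CPM at 8 hpf, 65.8 and 84.4 at 11 hpf, and 24.6 and 16.9 at 14 hpf. In the knockdown it stood at 8.83 and 9.35 CPM at 14 hpf, lower where a delay past the peak would give higher levels. A direct role of BHIKHARI in these genes was not tested, and an effect of this LNA other than on BHIKHARI cannot be told apart from it, because the series holds 1 knockdown LNA sequence.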

How the results depend on the processing

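The average over 11, 14 and 18 hpf and the shared calls without each library are the tests here chosen only after the data were seen. The fall of BHIKHARI_LTR kept its direction and its call at each time and on average under every alternative run, except with the 11 hpf groups fitted alone (log2 fold change -1.8, adjusted p = 1). No named knockdown gene reversed. Of 58 named knockdown calls, 28 to 58 were kept without a library, 55 by DESeq2 and 56 under RLE or upper quartile scaling; 34 of 57 were kept with groups fitted alone. A library left alone in its group was assumed to vary like the others. The cause was not tested for any change below, except that fitting groups alone leaves fewer samples to estimate the spread. Deviations of same-numbered libraries of a time correlated over genes at r of 0.37, 0.61 and 0.21 at 8, 11 and 14 hpf but 0.09 at 18 hpf, and 13 of 28 pairs of groups were over 0.1. The main fit did not pair the samples, since not every pair of groups was over 0.1. Pairs of groups from different times say little about pairing within a time. Shared handling at 8, 11 and 14 hpf therefore stays open, and the counts with a replicate block within each time are given beside the others. The counts of 0 genes at 11 and 14 hpf and for the difference between times are those without a block.

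For genes called at 8, 11, 14 and 18 hpf, on average and for the difference between times, no filter beyond 1 count gave 314, 92, 144, 121, 1038 and 77, and a replicate block within each time gave 603, 117, 305, 115, 2034 and 93. DESeq2 gave 110, 9, 10 and 5 at the 4 times and 3 for the difference. A replicate block gave 1 at 11 hpf, 1 at 14 hpf, 484 on average and 1 for the difference. Groups fitted alone gave 3 at 8 hpf, 55 at 14 hpf and 115 at 18 hpf, upper quartile scaling gave 1 at 11 hpf, and the average over 11, 14 and 18 hpf gave 55. The share of falls among genes called on average was 53.1% with a replicate block within each time and 65.7% with a replicate block. In controls 1209 genes were called from 11 to 14 hpf without the filter and 4093 from 14 to 18 hpf with groups fitted alone. Calls shared between times were 9 by DESeq2 and 1 with a replicate block.

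For families at 8, 11, 14 and 18 hpf and on average, no filter gave 12, 3, 12, 9 and 36, and a replicate block within each time 19, 3, 9, 2 and 63. Groups fitted alone gave 0, 5 and 2 at 11, 14 and 18 hpf, DESeq2 gave 4 at 8 hpf, a replicate block gave 13 on average, and the average over 11, 14 and 18 hpf gave 1. For lists, an estimated correlation gave 0 at every time and on average, fry gave 0 at 11, 14 and 18 hpf and 1 on average, and a filter of at least 1 CPM in at least 4 libraries gave 3 on average. Ribosomal protein genes at 11 hpf reversed without knockdown 11 hpf replicate 2 (adjusted p = 0.027), with adjusted p-values from 5e-12 (without knockdown 11 hpf replicate 1) to 0.35 (without control 11 hpf replicate 1) over the libraries left out.

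Without each library in turn, called genes ranged from 16 to 121 at 8 hpf, 0 to 75 at 11 hpf, 0 to 13 at 14 hpf, 0 to 5 at 18 hpf, 144 to 965 on average and 0 to 0 for the difference between times. In controls they ranged from 2716 to 5704, 98 to 774 and 636 to 2477 over the successive intervals. Families ranged from 1 to 3 at 8 hpf, 1 to 2 at 11 hpf, 1 to 2 at 14 hpf, 1 to 1 at 18 hpf and 4 to 29 on average. The log2 fold change of BHIKHARI_LTR ranged from -2.07 to -1.92, -2 to -1.56, -2.06 to -2.01 and -1.55 to -1.48 at the 4 times and from -1.88 to -1.77 on average. Called lists ranged from 0 to 5, 1 to 10, 3 to 7 and 2 to 4 at the 4 times and from 4 to 8 on average, and shared calls from 0 to 47. The libraries behind these ends include knockdown 8 hpf replicate 1 (16 genes at 8 hpf), knockdown 11 hpf replicate 1 (75 genes at 11 hpf, 965 on average) and knockdown 14 hpf replicate 1 (144 on average).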

Other observations

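The slower development weighed below was proposed after the libraries had been compared by principal components, and no test below was chosen after its own result was seen. Beyond the genes of the report, the controls between 8 and 11 hpf changed in many repeat families, with 108 of 862 called, 20 higher and 88 lower, and 54 when adjusted over families alone. Hox genes rose in 12 of 15 cases and 1 fell (camera adjusted p = 2e-06, adjusted p = 0.19 with an estimated correlation). Neurogenesis genes rose in 18 of 28 cases and 3 fell (adjusted p = 1.8e-05, estimated adjusted p = 0.24), among them NEUROD4, a driver of neuronal differentiation (7.61, SE 0.47). From 11 to 14 hpf 4 of 23 blood and vessel genes rose (adjusted p = 0.0013, estimated adjusted p = 0.14), among them SPI1 of the myeloid lineage (4.17, SE 0.65) and the endothelial cadherin cdh5 (2.78, SE 0.58). From 14 to 18 hpf 36 families changed, 17 higher and 19 lower, and 18 when adjusted over families alone.

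The delay that best matched the average change of 13649 genes to the trend of the controls was 0.41 h, with 0.21 to 0.63 h when a library was left out. At single times it was 0.36 h at 11 hpf and 0.93 h at 14 hpf, each from the controls before and after. Slower development of the knockdown embryos, as a candidate explanation, is weighed by the 69.4% of called genes that differed in the direction of earlier controls, which leaves it open. With the trend taken out, the median of ribosomal protein genes went from -0.14 to -0.07 and that of neurogenesis genes from -0.20 to -0.02.

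Regroupings of the libraries within each time were also counted for families, BHIKHARI_LTR and lists. For the 8 families called on average, 4 of 100 regroupings, the real one included, gave as many, and 45 was the highest other count. Chance is not excluded for this count, because a split by replicate number alone called 11 families. The log2 fold change of BHIKHARI_LTR had a size of 1.83, reached by 1 of 100, the real one, with 1.49 as the highest other. If the libraries of a time are interchangeable, chance can be excluded for this fall. Chance cannot be excluded for the count of 5 lists, since 40 of 100 regroupings gave as many and the highest other was 12. Splitting all libraries by replicate number called 228 genes, 11 families and 9 lists.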
